A study of Mus musculus with 9 samples.

How the data were processed

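RNA was measured in 9 libraries of mouse blastocysts in 4 groups: DMSO (n = 2), CAY (n = 2), NC (n = 2) and siScd1 (n = 3, numbered 1, 3 and 4 in the labels). Per the labels' protocols, embryos were treated at the zygote stage and kept in KSOM medium without albumin until 4.5 dpc, cDNA was made from lysed embryos with Superscript II, amplified with a PCR polymerase, cut into libraries with a transposase kit and sequenced as read pairs. Such reads carry no molecular identifiers, so counts after amplification are not counts of molecules. The authors deposited raw counts per gene in 2 tables, 1 per experiment. Per the submitters' processing notes, the tools were fastp 0.23.2, STAR 2.7.10a and featureCounts 2.0.1, with the genome build GRCm39. Whether the counting used strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart, which applies to the closely packed mitochondrial tRNA genes. Gene positions are those in the deposited count tables.

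Each table held 40834 genes. The rows of 6 very long genes were broken over several lines in both tables, and these genes were left out, with 44 rows of the inhibitor table and 25 of the knockdown table. Protein genes of the mitochondrial genome were not analysed here: of that genome the tables list 24 rRNA and tRNA genes. Total counts were 7671412 and 6734475 (DMSO), 6889881 and 6998265 (CAY), 13380258 and 9143391 (NC) and 8065957, 20804064 and 16655518 (siScd1). Replicates of a group differed by far more than sampling noise, with a chi-square per degree of freedom from 21.2 to 51.8, so that no library was taken for a copy of another. This does not show that they came from separate cultures.

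Tests were run on the deposited counts in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr with the groups), with each experiment fitted alone and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. The SE of a fold change was its size divided by the root of the F statistic. The common biological coefficient of variation was 38.8% in the inhibitor experiment and 31.5% in the knockdown experiment. CPM values were scaled by TMM within an experiment. The difference between the interventions was a contrast in a fit of all 9 libraries. Overlaps were tested with Fisher's exact test, and the correlation of fold changes, from log2 CPM with a prior count of 2, against all 60 relabellings of libraries within the experiments.

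Before the data were examined, 34 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The lists covered lipid metabolism, stress responses, cell lineages, other cell types and housekeeping processes. Of 867 list entries 847 matched a gene in the tables, 13 of them through a synonym in a RefSeq table of GRCm38.p6, which served for names alone. Lists with 5 or more tested genes were tested with limma 3.58.1 camera with a preset correlation of 0.01, two-sided, adjusted over the lists. This left 30 lists in each experiment, with 3 under that number and the list of mitochondrially encoded genes not tested. The rule named Scd1 to Scd4, then per experiment up to 10 called genes in each direction with a mean of at least 5 CPM, a symbol that is not of the predicted kind and no overlap between groups. Where fewer than 5 passed in a direction, the 5 of smallest p were named as not passing. Up to 4 members of smallest p were named for a list, and for the difference the 5 of smallest p in each direction. Where a gene is adjusted over a list alone, its p was adjusted within that list, with no correction for the number of lists. Such passes are weaker than calls over all genes tested.

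The alternatives were DESeq2 1.42.0, limma-voom, RLE scaling, library totals, other count filters, a fit of all 9 libraries, a size threshold, leaving out mitochondrial and ribosomal protein genes, a replicate block, an estimated correlation and fry for the lists, and leaving out each library in turn. Leaving out genes on the X and Y chromosomes was added after the data were seen. In fits that leave a group with 1 library, that library is assumed to vary like the others. The tests were also run on simulated data, counts with 200 changed genes in 5 draws per experiment, in which genes varied independently of each other. In the inhibitor design, over 11709 genes, 56.9% of genes changed 4-fold and 15.2% of those changed 2-fold were recovered. In the knockdown design, over 13311 genes, these shares were 71.4% and 20.5%. A list raised 2-fold was called by camera with the preset correlation in 5 of 5 draws in both designs. Unchanged genes were called at 5.6 and 4.4 per draw. With an estimated correlation the raised list was called in 0 of 5 draws in the inhibitor design and 4 of 5 in the knockdown design.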

Results

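Gene expression was measured by RNA sequencing of mouse embryos of the C57BL/6J strain that had been cultured from the zygote to the blastocyst stage, 4.5 days post coitum (dpc). The blastocyst holds an outer layer, the trophectoderm, and inner cells that form the epiblast and the primitive endoderm. The 9 libraries fell into 2 experiments on Scd1, which encodes stearoyl-CoA desaturase 1, an enzyme that puts a double bond into saturated fatty acids. In the inhibitor experiment, 2 libraries treated with CAY, which the labels describe as inhibition of Scd1, were set against 2 libraries treated with the solvent DMSO. In the knockdown experiment, 3 libraries of embryos with Scd1 knocked down (siScd1) were set against 2 libraries of a negative control knockdown (NC). Total counts ran from 6734475 to 7671412 per library in the inhibitor experiment and from 8065957 to 20804064 in the knockdown experiment. The labels do not say how many embryos went into a library or whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The libraries differed in sex-linked transcripts. CAY replicate 2 held 2 counts over the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, against 871 to 1172 in the other libraries of its experiment, and siScd1 replicate 1 had 10.9 CPM of Xist, the transcript of the inactive X chromosome, against 89.9 to 235 CPM in the other libraries of its experiment.

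The first question was whether the transcript of the targeted gene was lower. RNA does not measure the activity of the enzyme, so for CAY this does not test whether Scd1 was inhibited. Scd1 lies on chromosome 19, from 44382889 to 44396148 on the minus strand of GRCm39, beside Scd2, Scd3 and Scd4. In the knockdown experiment Scd1 fell to 0.217 times its NC level, from 99.0 ± 31.7 CPM (SD, n = 2) to 21.4 ± 3.80 CPM (SD, n = 3), a log2 fold change of -2.21 ± 0.28 (SE) with an adjusted p of 0.00234 in edgeR's quasi-likelihood test. Every siScd1 library lay below every NC library. Such separation says little by itself: 18.8% of genes tested had it in either direction, where 20% were due by chance. The fold change stayed between -2.49 and -1.84 when any 1 library was left out, but the adjusted p was 0.0600 without siScd1 replicate 3. With CAY, Scd1 was at 502 ± 55.2 CPM against 399 ± 55.1 CPM with DMSO (SD, n = 2 each), a log2 fold change of 0.33 ± 0.20 that did not pass (edgeR adjusted p = 0.765). Scd2, a second desaturase gene, had log2 fold changes of 0.75 ± 0.20 with CAY and 0.76 ± 0.32 with siScd1, and neither passed over all genes tested (edgeR adjusted p = 0.591 and 0.850). The CAY value stayed between 0.60 and 0.89 when any 1 library was left out, while the siScd1 value, whose groups overlapped, was 1.51 without NC replicate 1 and 0.28 without NC replicate 2. Scd2 passed with CAY when adjusted over the list of desaturation genes alone (adjusted p = 0.0392). Degs1, a desaturase gene of ceramide synthesis, was at -0.68 ± 0.25 with siScd1 and passed when adjusted over the same list alone (edgeR adjusted p = 0.0480). That list holds Scd1 itself, whose small p eases the adjustment for Degs1. Over all genes tested Degs1 did not pass. Scd3 did not pass in either experiment, and Scd4 had too few counts to be tested.

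**Figure D1:**
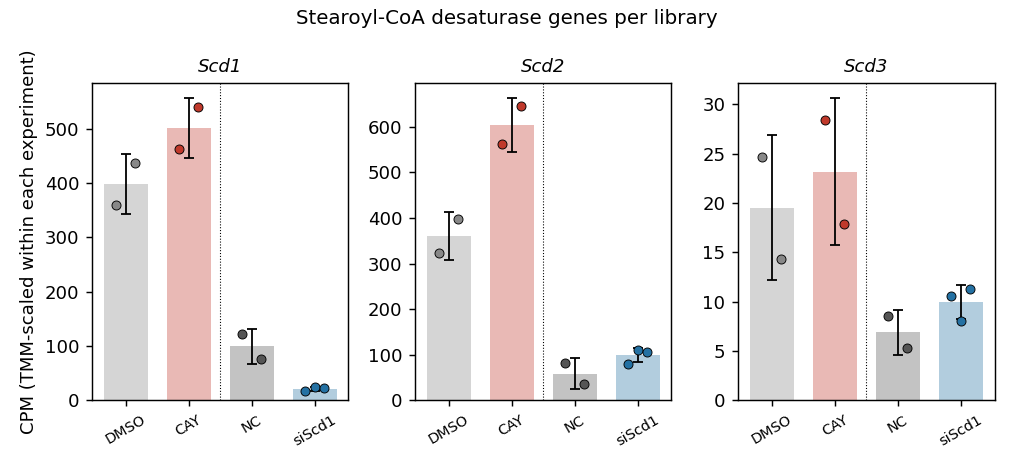
Expression of Scd1, Scd2 and Scd3 in CPM (vertical axes, from 0) in each of the 9 libraries (points), by group (horizontal axes), with group means (bars) and SD (lines); counts were scaled within each experiment, and the dotted line parts the experiments. The siScd1 libraries average 21.4 CPM of Scd1 against 99.0 CPM in NC.

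The knockdown was then compared with its control over all 13960 genes tested. It changed 6 genes, all of them lower. After Scd1, these were Il6, a cytokine gene, with a log2 fold change of -2.89 ± 0.49, the glutathione transferase gene Gsta1 with -3.03 ± 0.54, Fam151a with -2.15 ± 0.39, and Magea8 with -2.13 ± 0.38, each with an edgeR adjusted p of 0.0429. The sixth was BC051665, chosen for naming after its values were seen, which fell from 3392 ± 1080 to 486 ± 302 CPM (edgeR adjusted p = 0.0142). Gsta1 and Magea8 have close copies in the genome, so their counts are uncertain, and Magea8 is on the X chromosome, whose reads the sex makeup of a library can move. The genes of smallest p that the rule for naming genes admits among those higher with siScd1 did not pass. They included Abcg1, a sterol exporter gene and target of the LXR receptors, at 1.76 ± 0.36, and Cd81, a tetraspanin gene, at 1.38 ± 0.30 (edgeR adjusted p = 0.140 and 0.184). Aldh1l1 at 1.51 ± 0.34, Prpf40b at 1.71 ± 0.43 and the mitochondrial tRNA gene TrnQ at 1.35 ± 0.35 did not pass either. Adjusted over the list of LXR targets alone, Abcg1 rose (adjusted p = 0.000420), while that list as a whole was not called by camera. In all, 740 genes had an unadjusted p under 0.05 where 698 were due by chance. Il6 stood at 25.5 ± 24.0 CPM in NC and had a fold change of -1.31 without NC replicate 2. Leaving out 1 library gave 30 called genes without NC replicate 1, 1 (Scd1) without NC replicate 2, and 14, 0 and 3 without siScd1 replicates 1, 3 and 4.

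Of 30 gene lists tested in the knockdown experiment, camera called 5 with its preset correlation, 1 higher and 4 lower. The list of p53 targets and apoptosis genes, which also holds general apoptosis genes such as Casp8 and Mcl1, was higher with siScd1, with 20 of 24 members above 0 and a median log2 fold change of 0.46 (camera adjusted p = 1.98e-06; adjusted p = 0.784 with an estimated correlation). Adjusted over the list alone, 3 members rose: Plk2 by 1.12 ± 0.31, Phlda3 by 1.06 ± 0.31 and the cell cycle inhibitor gene Cdkn1a, whose groups overlapped, by 1.11 ± 0.35 (0.73 without NC replicate 2). Without siScd1 replicate 4 the median of the list was 0.24. Trophectoderm markers were lower, with 18 of 22 members below 0 and a median of -0.33 (camera adjusted p = 0.000111; adjusted p = 0.738 with an estimated correlation), and of -0.14 without NC replicate 2. Adjusted over the list alone, 1 of them, the transcription factor gene Gata2, fell, with -1.16 ± 0.29 (-0.74 without NC replicate 2), while Lgals1 at -0.63 ± 0.24 and Tspan8 at -0.57 ± 0.24 did not pass. The lists of ferroptosis-related genes (median -0.35), ATF4 targets (median -0.33) and ribosomal protein genes (median -0.10) were also called lower, with camera adjusted p of 0.00366, 0.00754 and 0.0195. With an estimated correlation their adjusted p were 0.784, 0.784 and 0.806. Among ATF4 targets Psat1, a serine synthesis gene, fell by 1.10 on the log2 scale, adjusted over the list alone (-0.32 without NC replicate 2), and among ferroptosis-related genes so did the iron exporter gene Slc40a1, with -2.66 ± 0.69, although its siScd1 and NC libraries overlapped and the value was -0.09 without NC replicate 2. None of the members named here passed over all genes tested. No list was called by fry's directional test (smallest adjusted p = 0.801), while its test for change in either direction gave adjusted p of 0.0184 for the desaturation genes and 0.00742 for the LXR targets, lists that both hold Scd1. Without NC replicate 2 the camera adjusted p was 0.663 for both the ferroptosis-related genes and the ATF4 targets, whose medians were then -0.02 and 0.13, and 0.143 for ribosomal protein genes, with a median of -0.08. Without siScd1 replicate 4 it was 0.278, 0.173 and 0.763, with medians of -0.20, -0.27 and 0.025, and without siScd1 replicate 1 it was 0.0941 for ribosomal protein genes, whose median stayed at -0.10. Without NC replicate 1 the ferroptosis median was -0.54 and the ATF4 median -0.775, and without siScd1 replicate 3 the ribosomal median was -0.28.

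The inhibitor experiment asked which genes differed between CAY and DMSO. The genes of smallest p among those higher with CAY belonged to the integrated stress response, in which the transcription factor ATF4 switches on amino acid and one-carbon metabolism, and to the unfolded protein response of the endoplasmic reticulum (ER). Atf3, a stress-induced transcription factor gene, was 22.3 times as high with CAY as with DMSO (log2 fold change 4.48 ± 0.59), and Trib3, a pseudokinase gene induced by ATF4, 14.1 times as high (3.81 ± 0.58). Herpud1, which acts in the breakdown of misfolded ER proteins, was 5.01 times as high, at 148 ± 13.2 CPM against 29.4 ± 11.1 CPM (SD, n = 2 each). Hspa5, the main ER chaperone gene, was 2.48 times as high, at 790 ± 129 against 318 ± 10.7 CPM. Shmt2, a mitochondrial one-carbon enzyme gene, was 4.33 times as high. None of these passed over the 12308 genes tested, where the smallest edgeR adjusted p was 0.104. The count of genes called was therefore 0 in edgeR, with 954 genes at an unadjusted p under 0.05 where 615 were due by chance. DESeq2 called 26 genes, 14 of them in these 2 lists, and limma-voom called 4. edgeR called 12 genes without CAY replicate 1 and 1, Herpud1, without CAY replicate 2. Lower with CAY at the smallest p was BC053393, outside the rule for naming genes and chosen after its values were seen, with -1.16 ± 0.19 (edgeR adjusted p = 0.256), and DESeq2 and limma-voom called it. The genes of smallest p that the rule admits among those lower with CAY did not pass either: the carbonic anhydrase gene Car4 (-1.70 ± 0.35), Hsd17b6 (-1.34 ± 0.28), the glycerol kinase gene Gk (-1.45 ± 0.30), Magec2 (-2.20 ± 0.48) and the mitochondrial tRNA gene TrnM (-1.17 ± 0.23). Gk and Magec2 are on the X chromosome, and CAY replicate 2 nearly lacked Y-linked reads. Their falls did not rest on that library, since both were also low in CAY replicate 1, which held 871 Y-linked counts. Gk was at 27.6 and 21.7 CPM in CAY replicates 1 and 2 against 74.9 and 60.1 in DMSO. Magec2 was at 4.53 and 7.25 against 20.3 and 34.0.

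**Figure D2:**
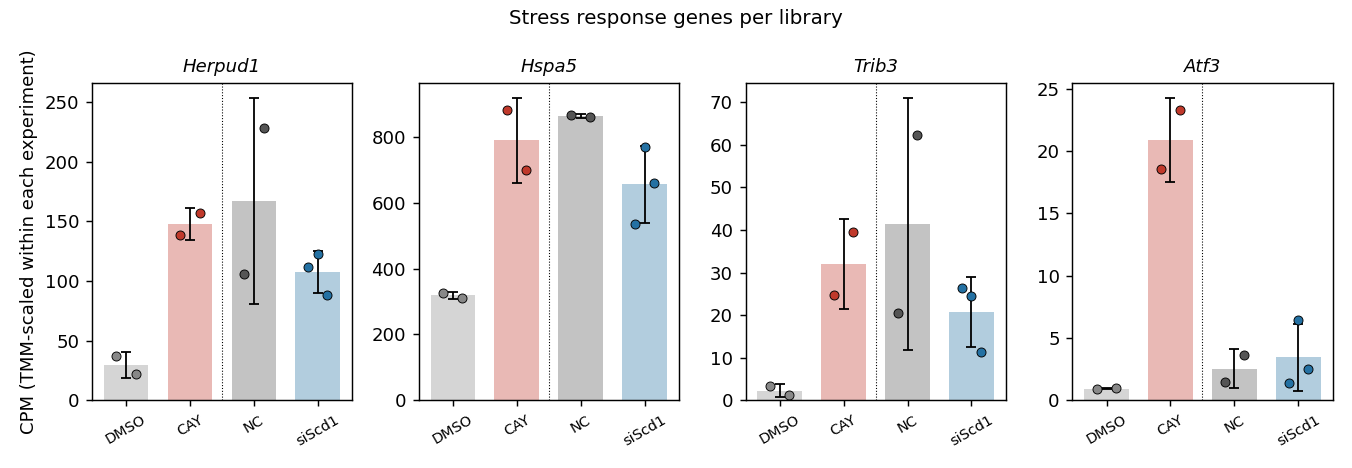
Expression of Herpud1, Hspa5, Trib3 and Atf3 in CPM (vertical axes, from 0) in each of the 9 libraries (points), by group (horizontal axes), with group means (bars) and SD (lines); counts were scaled within each experiment, and the dotted line parts the experiments. Herpud1 averages 148 CPM with CAY and 29.4 CPM with DMSO.

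As groups, the stress genes were higher with CAY. Of 25 ATF4 and integrated stress response genes, 22 were above 0, with a median log2 fold change of 1.37 (camera adjusted p = 9.98e-21; adjusted p = 0.249 with an estimated correlation), and 13 rose when adjusted over the list alone, among them Mthfd2 with 1.99 ± 0.37. Of 25 ER chaperone and unfolded protein response genes, 22 were above 0, with a median of 0.50 (camera adjusted p = 3.47e-15; adjusted p = 0.249 with an estimated correlation), and 11 rose when adjusted over the list alone, among them Manf with 1.34 ± 0.25 and Hsp90b1 with 1.22 ± 0.22. None of either list passed over all genes tested. Both lists were called in each of the 4 fits that left out 1 library. DMSO stood below the other control for these genes: in a fit of all 9 libraries Herpud1 averaged 27.9 CPM in DMSO and 174 CPM in NC. Heat shock genes were not called (median 0.12, mean 0.605, camera adjusted p = 0.540).

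**Figure D3:**
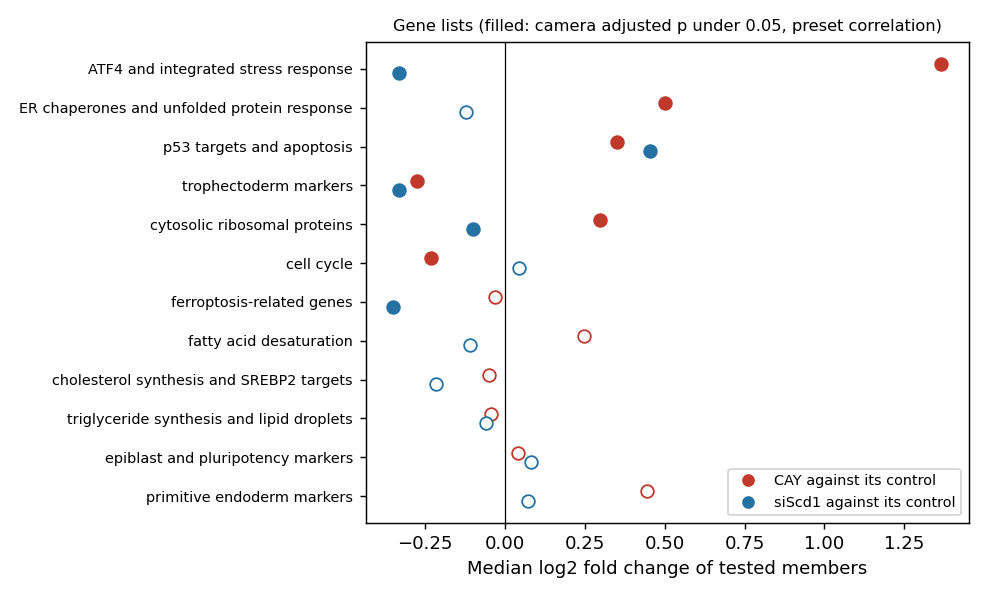
Median log2 fold change (horizontal axis) of the tested members of the called gene lists and of lists of lipid and lineage genes (vertical axis) for CAY against DMSO (red) and siScd1 against NC (blue); filled points passed camera with the preset correlation. The ATF4 list lies at 1.37 with CAY and at -0.33 with siScd1.

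In all, camera called 6 of 30 lists with CAY, 4 higher and 2 lower. Ribosomal protein genes were higher, with 72 of 77 above 0 and a median of 0.30 (camera adjusted p = 1.98e-12; adjusted p = 0.746 with an estimated correlation). Rpl8 at 0.75 ± 0.21 and Rps12 at 0.72 ± 0.20 had the smallest p with Rpl10 and Rpsa, and none of the list passed when adjusted over the list alone. In the fit of all 9 libraries 70 of the 77 were lower in DMSO than in NC. The list of p53 targets and apoptosis genes was higher, with 19 of 23 above 0 and a median of 0.35 (camera adjusted p = 0.000864; adjusted p = 0.746 with an estimated correlation). Pmaip1 at 1.09 ± 0.35 and Mdm2 at 0.68 ± 0.24 (0.62 and 0.43 without CAY replicate 2) were among its members of smallest p, and none passed over the list alone. Cell cycle genes were lower, with 24 of 30 below 0 and a median of -0.23 (camera adjusted p = 0.00889; adjusted p = 0.746 with an estimated correlation). The cyclin gene Ccne1 was at -0.80 ± 0.24, and none passed over the list alone. Trophectoderm markers were lower, with 15 of 23 below 0 and a median of -0.27 (camera adjusted p = 0.0195; adjusted p = 0.746 with an estimated correlation). Adjusted over the list alone, Lgals1 with -0.80 ± 0.19 and the placental gene Plac1 with -1.14 ± 0.27 fell, while Gata3 at -0.74 ± 0.26 (-0.32 without DMSO replicate 2) did not pass. No list was called by fry's directional test (smallest adjusted p = 0.151) or by its test for change in either direction. The p53 and apoptosis list and the trophectoderm list had camera adjusted p of 0.363 and 0.581 without CAY replicate 2, the library nearly lacking Y-linked reads, with medians of 0.22 and -0.22, and 0.0655 and 0.0914 without DMSO replicate 1, with 0.19 and -0.17. The p53 and apoptosis median was 0.66 without CAY replicate 1. Cell cycle genes had 0.0820 without CAY replicate 1, where the median stayed at -0.23, and 0.0649 without DMSO replicate 2, where it was -0.12. Lists of lipid metabolism were not called in either experiment by camera or by fry's directional test with all libraries. With 1 library left out, camera called some of these lists, each in at least 1 fit. Desaturation genes, a list that holds the knocked-down Scd1, were called lower with siScd1. With all libraries 4 of the 8 tested members of that list were above 0, and its median was -0.11. Cholesterol synthesis genes were called lower with siScd1 but higher with CAY, and beta-oxidation genes lower with CAY. Cholesterol synthesis genes had medians of -0.05 with CAY and -0.22 with siScd1, and genes of triglyceride synthesis and lipid droplets had -0.04 and -0.06; with CAY the test statistic of both lists had the opposite sign to the median.

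Last, the 2 interventions were compared with each other. In a fit of all 9 libraries the CAY effect differed from the siScd1 effect for 8 of 13950 genes in edgeR. Among them was Scd1, the gene that the knockdown itself targets. Scd1 differed by 2.53 ± 0.36 on the log2 scale (edgeR adjusted p = 0.0148), a call that was lost without DMSO replicate 1 (2.39, adjusted p = 0.0625) and without siScd1 replicate 3 (2.65, adjusted p = 0.0575). Herpud1 by 2.96 ± 0.46, Trib3 by 4.81 ± 0.76 and Mthfd2 by 2.88 were higher with CAY relative to siScd1, as were Tceal8, Flrt3 and Abhd18, while the sugar transporter gene Slc5a4b was lower, with -3.83 ± 0.59. The next genes lower with CAY relative to siScd1 did not pass: Cald1 at -2.58 ± 0.59, Dkk1, an inhibitor of Wnt signalling, at -3.55 ± 0.83 (-2.13 without DMSO replicate 1), Btbd3 at -3.07 ± 0.74, and Vim, a mesenchyme marker gene with 0 counts in CAY and 37 in DMSO. Without DMSO replicate 2, Dkk1 and Vim passed (adjusted p = 0.0189 and 0.00415), and without DMSO replicate 1 Vim had an adjusted p of 1.00. The count was 4 without DMSO replicate 1, 3 of them among the 8, 35 and 17 without CAY replicates 1 and 2, 17 and 2 without NC replicates 1 and 2, and 0 and 3 without siScd1 replicates 3 and 4. At an unadjusted p under 0.05 there were 880 genes, where 698 were due by chance, and DESeq2 called 36. No gene was called by edgeR in both separate fits, and DESeq2 called 1 in both. The overlap was tested over genes, which share libraries and are not independent, so its p-values may be too small. At an unadjusted p under 0.01 in both experiments, 5 genes were lower in both where 0.77 were due by chance (Fisher's exact test, two-sided, p = 0.00100): BC053393, Rab3il1, BC051665, Dglucy and Alppl2. Single libraries set the size for some of them: BC051665 with CAY was at -0.58 without DMSO replicate 2, Rab3il1 with siScd1 at -0.59 without NC replicate 2, Alppl2 with siScd1 at -2.21 without siScd1 replicate 3, and Dglucy had 1.13 and 0 CPM in the CAY libraries. Gm5662 was the 1 gene higher in both, where 0.51 were due by chance (Fisher's exact test, two-sided, p = 0.400), and 3 genes, Slc5a4b, Mthfd2 and Psat1, had fold changes of opposite sign where 1.27 were due, which was not tested. Across 11902 genes, which are not independent replicates, the fold changes of the experiments had a Pearson r of 0.099 and a Spearman rho of 0.118. In an exact permutation test over 60 relabellings of the libraries, two-sided, these had p of 0.133 and 0.200, where the smallest possible p was 0.0333.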

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

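Of the tests of explanations below, those of handling stress and of a response shared with the knockdown were chosen after list results had been seen.

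The effects of the interventions differed, by a test of the difference itself in edgeR, for 8 genes and, by camera with the preset correlation, for 3 lists. The genes were Scd1 and Flrt3 (adjusted p = 0.0148), Slc5a4b, Herpud1, Tceal8 and Trib3 (adjusted p = 0.0159), and Abhd18 and Mthfd2 (adjusted p = 0.0175). Scd1 is the gene that the knockdown targets, so its call is a check of the knockdown rather than a finding on how the responses differ. Flrt3 had 0 counts in DMSO and 122 in CAY, at least 42.2-fold higher against a floor of 3 counts over the DMSO group. Abhd18 had 1 count in DMSO and 143 in CAY. In the fit of all 9 libraries Flrt3 averaged 8.2 CPM in CAY, 44.6 in NC and 64.1 in siScd1, so CAY lay below both knockdown groups. Abhd18 averaged 9.6 CPM in CAY, 4.4 in NC and 2.6 in siScd1. The low DMSO level thus sets much of both differences. The lists were ATF4 and integrated stress response genes, with a median difference of 1.54, ER chaperones, with 0.87, and ribosomal protein genes, with 0.44. With an estimated correlation their adjusted p were 0.118, 0.118 and 0.864. Explanations for the ribosomal protein genes were not tested.

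The stress genes higher with CAY were set against 3 explanations. A single CAY library is argued against, since the lowest median over the 4 pairs of a CAY and a DMSO library was 0.83 on the log2 scale. Stress from handling that raises immediate early and heat shock genes as a set is argued against as the whole cause. These genes had a median of 0.18 ± 0.10 (bootstrap SE over genes, not libraries) where the stress lists together had 0.97 ± 0.15. Over the 4 pairs of libraries their median was at most 0.224. The mean of the heat shock genes, 0.605, lay above their median of 0.12, so handling stress seen in a few such genes alone was not excluded. A response to lower Scd1 function that the knockdown shares stays open: the stress lists had a median of -0.26 ± 0.10 with siScd1, but over the 6 pairs of a siScd1 and an NC library the medians reached 0.19. An effect of CAY apart from Scd1 was not tested, because the design holds 1 compound. The DMSO libraries themselves may be low for these genes, since they lay below NC as well.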

How the results depend on the processing

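The counts of called genes depended on the method. For CAY against DMSO edgeR called 0 genes, DESeq2 26, limma-voom 4, edgeR without a low-count filter 50, with a mean of at least 5 CPM 1 (Herpud1), and with all 9 samples in the fit 17. Leaving out 1 library gave 0 to 12. For siScd1 against NC edgeR called 6, DESeq2 22, library totals 2, no low-count filter 62, a mean of at least 5 CPM 11, and all 9 samples 1. Leaving out 1 library gave 0 to 30. For the difference the count was 8, with DESeq2 36, all 8 among them, and 0 to 35 with 1 library left out. The overlap was 0, and 1 with DESeq2 calls and 6 at an unadjusted p under 0.01. The causes were not tested.

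Replicate numbers 1 and 2 occur in both DMSO and CAY, and nothing says that they mark a shared batch. The deviations of same-numbered samples correlated at 0.0284 across genes. With the replicate block 36 genes were called with CAY, 19 higher and 17 lower, and 6 lists. For siScd1 against NC no paired analysis was possible because these groups share 1 number.

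Of the called lists, 6 with CAY and 5 with siScd1, camera with an estimated correlation and fry's directional test kept 0 in both experiments. With all 9 samples siScd1 gave 9 lists, and leaving out 1 library gave 4 to 8. In the inhibitor design the estimated correlation also missed a simulated 2-fold list in each of 5 draws. That loss says little for the ATF4 and ER chaperone lists with CAY, whose estimated correlations were -0.0017 and 0.0176. The simulated genes varied independently, so the draws do not cover ribosomal protein genes (0.2201) or p53 and apoptosis genes (0.1578). In the knockdown design the simulated list was called in 4 of 5 draws, so the loss of the 5 siScd1 lists cannot be set aside in this way. Scd1 with siScd1 ran from -2.49 to -1.84 with 1 library left out. Some values changed sign with 1 library left out. Scd3 with CAY ran from -0.134 without CAY replicate 1 to 0.693 without DMSO replicate 1, with -0.103 without DMSO replicate 2. Ribosomal protein genes with siScd1 ran from -0.278 without siScd1 replicate 3 to 0.025 without siScd1 replicate 4. With siScd1, from the fit without NC replicate 1 to that without NC replicate 2, the ATF4 list ran from -0.775 to 0.131, Trib3 from -1.60 to 0.021, Hmox1 from -1.338 to 0.020 and Elf5 from -1.328 to 0.103. For genes named or on named lists, 891 values kept direction and side of the threshold, 54 no longer passed and 63 newly passed. Only genes called in the main fits could lose a call: 0 with CAY, 6 with siScd1 and 8 for the difference. Most of the 891 values therefore belong to genes that had not passed and stayed so, and do not show that the calls are stable. The correlation of fold changes was above 0 in each alternative run, from 0.0165 to 0.1276.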

Other observations

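The tests in this part were chosen after the results had been seen, except that on pairs of single libraries for the trophectoderm markers, where the rule of 2 bootstrap SE was set after its values had been seen.

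The control groups differed in the level of the stress genes. In the fit of all 9 libraries Herpud1 averaged 27.9 CPM in DMSO, 140 in CAY, 174 in NC and 112 in siScd1, and Trib3 averaged 2.11, 30.4, 43.1 and 21.5 CPM. Of 26 ATF4 and integrated stress response genes, 23 were lower in DMSO than in NC, with a median log2 difference of -1.51. Ribosomal protein genes, with 70 of 77 lower in DMSO and a median of -0.70, ER chaperone genes, with 18 of 25 and -0.94, and trophectoderm markers, with 15 of 23 and -0.48, also stood lower in DMSO. Atf3 averaged 0.876 CPM in DMSO, 19.8 in CAY, 2.64 in NC and 3.59 in siScd1. The experiments also differed in Scd1, with 379 CPM in DMSO and 103 in NC. DMSO and NC differed for 1755 genes in edgeR, and the first principal component, with 41.4% of the variance, parted the experiments, so that treatment of the controls and experiment cannot be told apart.

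Some lineage genes outside the called lists stood apart without passing over all genes, and those of the primitive endoderm list did not pass over that list alone either. With CAY the primitive endoderm list had a median of 0.44 (camera adjusted p = 0.132), with Sparc at 0.88 ± 0.25, Pdgfra at 1.37 ± 0.44 and Gata6 at 0.68 ± 0.23. Over pairs of a CAY and a DMSO library the list median was 0.068 and 0.383 for CAY replicate 1 and 0.468 and 1.01 for CAY replicate 2, the library nearly lacking Y-linked reads, and without replicate 2 the adjusted p was 0.777. The list was called in 1 of the 4 fits that left out 1 library. With siScd1 that list had a median of 0.07, with 13 of 23 above 0 (camera adjusted p = 0.278) and pair medians of 0.291 to 0.559 against NC replicate 1 and -0.257 to -0.138 against NC replicate 2. Gata6 with siScd1 was at 0.68 ± 0.27 and Sparc at 0.68 ± 0.28. Ezr, which encodes the membrane linker ezrin, was at 1.02 ± 0.24 with CAY, passing over the list of cavity and junction genes alone, and at 0.74 ± 0.27 with siScd1, not passing. Its list did not rise as a whole. With CAY 14 of 27 members were below 0, with a median of -0.03 (camera adjusted p = 0.892). With siScd1 16 of 27 were below 0, with a median of -0.12 (camera adjusted p = 0.410). Of genes marking other cell types, in lists too short to test, the mesenchyme marker Vim was at 1.19 ± 0.35 with siScd1 and the macrophage marker Cd68 at -1.15 ± 0.38 with CAY.

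Trophectoderm markers were called lower in both experiments with the preset correlation, but with an estimated correlation the adjusted p was 0.746 with CAY and 0.738 with siScd1, and with CAY the adjusted p was 0.581 without CAY replicate 2 and 0.0914 without DMSO replicate 1. A single siScd1 library as the source in the knockdown experiment is argued against: with each of the 3 left out in turn, the median lay below 0 by more than 2 bootstrap SE over genes, and the highest was -0.235 ± 0.08, while over single pairs of a siScd1 and an NC library it did so in 4 of 6, with the highest at -0.094 ± 0.15. A single NC library as the source was not tested in this way, and without NC replicate 2 the median was -0.14. A single CAY library stays open, since the highest median with either left out was -0.219 ± 0.155, and over the 4 pairs of a CAY and a DMSO library the median was below 0 but in 0 of them by more than 2 bootstrap SE, with the highest at -0.169 ± 0.233. A smaller share of trophectoderm cells may also lie behind it and was not decided. It would raise the markers of the inner lineages alike, and the epiblast medians were 0.04 ± 0.12 with CAY and 0.08 ± 0.09 with siScd1, while primitive endoderm minus epiblast was 0.402 ± 0.23 with CAY, where the primitive endoderm list differed between the CAY libraries, and -0.01 ± 0.15 with siScd1.

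CAY replicate 2 held 2 counts of the 4 Y-linked genes where the other libraries of its experiment give 1017 at its depth, with a lower Poisson limit of 955 that covers counting error alone. This argues against low depth. Its Xist level, 510.7 CPM, was the highest of the 4 libraries of the experiment, which is consistent with a library without male embryos. A candidate explanation is that each library holds few embryos, so that sex makeup differs between libraries. Leaving out genes on X and Y kept the count of genes called at 0 with CAY and gave 5 with siScd1. Without CAY replicate 1 the genes called with CAY were 12, and they included Ddx3y, Eif2s3y and Uty.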
